A study of Mus musculus with 8 samples.

How the data were processed

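Ribosome-bound RNA from hypocretin neurons (4 immunoprecipitates) and RNA of the matching unbound fractions (4 samples) were measured on 8 mouse Affymetrix arrays, 1 per sample, after amplification over 2 cycles per the labels' protocols. Each replicate is a separate preparation of pooled mice. The authors deposited 1 normalized value per probe set and array, used here as log2 values. GCRMA, a background correction and normalization for such arrays, is named in the submitters' processing notes, and the design text records that each group was normalized separately; its version is not given in the sources used here. The lowest value was 2.21 in the immunoprecipitates and 2.14 in the unbound fractions.

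Because the groups were normalized apart, 1 constant per group was subtracted so that 18 biotinylated hybridisation controls had equal means, a step the design text recommends. As deposited, these controls differed by 0.02 on the log2 scale (immunoprecipitate minus unbound). The 64 control probe sets were left out. Other probe sets at or above a linear value of 50 on at least 4 arrays, 17865 in all, were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with no block. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. Adjusted p-values in the text come from limma for genes and from limma's camera for lists. Where a group lay under 50 on all 4 arrays, the fold is given as a bound, computed from the other group's mean against 50, shifted as its group was. Where only some arrays of a group reached 50, values under 50 were raised to it for the fold, which is then also given as at least. The number of arrays limits the precision.

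Gene names came from the platform annotation supplied with the series. Of all probe sets 34945 had 1 gene symbol, 932 had several and 9160 were not listed, and 0 symbols were updated. Among tested probe sets these numbers were 16367, 465 and 1033. A gene was represented by its probe set with the highest mean over the 8 arrays, which gave 10398 genes. Of 4000 genes with several tested probe sets, 2624 had the same call throughout and 44 had calls in both directions.

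The design, the tests, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule names Hcrt and Lhx9, the 15 genes with the largest fold higher and the 10 with the largest fold lower among called genes whose groups did not overlap, and up to 4 called members of each list with the largest change, or members with the highest mean up to 2 where fewer than 2 were called. Genes outside it are marked in the text as named after their values were seen. Lists were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over 28 lists, and again with an estimated correlation. They were also tested with fry, which asks whether a list moves one way from 0 and makes no comparison with other genes. The list of erythrocyte genes had fewer than 3 tested members and was not tested. Some lists share genes, among them Pcsk1, Scg2 and Vgf in the hypocretin and dense-core vesicle lists.

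Replicate numbers in the labels join the fractions of 1 preparation. Deviations from the group means correlated at 0.44, 0.33, 0.25 and 0.59 across genes between same-numbered arrays. For replicate 2 the correlation with another number reached 0.26, under its own 0.33. For replicate 3 it reached 0.26, against its own 0.25. The values themselves therefore bear out the pairing for replicates 1 and 4, less clearly for replicate 2 and not for replicate 3. A fit with the replicate block was run as an alternative. It called 931 probe sets higher and 8192 lower. The other alternatives were no shift, median centring, quantile normalization, no filter, a minimum of 100, no trend, no fold threshold, a 4-fold threshold, the mean of a gene's probe sets, and leaving out each array. A shift on 24 poly-A controls, and leaving out both arrays of replicate 1 or of replicate 4, were chosen after seeing the data.

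RNA integrity was compared as the 3' minus 5' signal of Actb and Gapdh with exact permutation tests, unpaired and paired by replicate. The fit was tested on simulated data with 17865 probe sets, where it recovered 66.7%, 76.1% and 95.5% of probe sets changed by 1.5, 2 and 3 on the log2 scale and called 6 of 17665 unchanged ones. A raised list was called, and 0 of 20 unchanged lists were. The simulated probe sets varied independently, whereas the estimated correlation within the real lists reached 0.76. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.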

Results

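Hypocretin neurons of the mouse hypothalamus were profiled by translating ribosome affinity purification, a method that tags the ribosomes of 1 cell type with a transgene and pulls down the RNA bound to them. The mice carried a bacterial artificial chromosome transgene named for Hcrt, the gene of the arousal peptides hypocretin-1 and hypocretin-2. Thalamus and hypothalamus were dissected together from adults of both sexes aged 6 to 12 weeks, and each sample pooled 5 mice. 4 immunoprecipitates, which hold the ribosome-bound RNA, were set against 4 unbound fractions of the same preparations, which stand for the RNA of the whole tissue. Each was hybridised to 1 Affymetrix mouse array. Between 33.6% and 34.8% of the probe sets on an immunoprecipitate array and between 40.5% and 40.9% on an unbound array lay at or above a linear value of 50. 17865 probe sets, which stand for 10398 genes, were tested. The number of arrays limits the precision of every value.

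The comparison sets RNA pulled down with the tagged ribosomes of hypocretin neurons against RNA of the whole tissue. Cell type and binding to ribosomes differ together between the fractions, so a fold cannot tell them apart. The immunoprecipitates also gave signal for genes of other cells. Oligodendrocyte genes averaged 8.79 to 10.18 on these arrays and astrocyte genes 7.26 to 8.76 on the log2 scale, where the minimum of 50 is 5.64. Whether this is carried-over RNA was not tested, since no precipitate from mice without the transgene was among the arrays. Hcrt stood at a log2 level of 15.36 ± 0.17 in the immunoprecipitate and 10.33 ± 0.55 in the unbound fraction (SD, n = 4 each). That is a log2 fold change of 5.02 ± 0.25 (SE), or 32.5-fold, with a limma adjusted p of 6.5e-07. On the log2 scale it was 5.95 after median centring and 3.06 on the poly-A controls, a scale added after seeing the data, and its call held on both. It was higher in 4 of 4 pairs of fractions from the same preparation, by 40.3-, 39.1-, 32.7- and 21.7-fold. Lhx9, a LIM homeobox transcription factor that the study's title names, was 4.23-fold higher (log2 fold change 2.08 ± 0.44 SE, limma adjusted p = 0.0022). The study picked Lhx9 from these samples, so its direction here is not independent evidence.

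Lhx9 was level across the immunoprecipitates (11.07 ± 0.07, SD, n = 4) and spread widely across the unbound fractions (8.99 ± 1.05, SD, n = 4). The fold within a pair was 2.81, 2.26, 4.52 and 11.1. A second Lhx9 probe set rose by 1.75 on the log2 scale (limma adjusted p = 0.0037), while another gave -0.02 (limma adjusted p = 0.98). On the log2 scale Lhx9 gave 3.0 after median centring, 2.81 after quantile normalization, 1.27 as the mean of its probe sets (limma adjusted p = 0.030) and 0.11 on the poly-A controls (limma adjusted p = 0.80). Over all 19 alternatives its adjusted p ran from 0.0004 to 0.80.

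**Figure D1:**
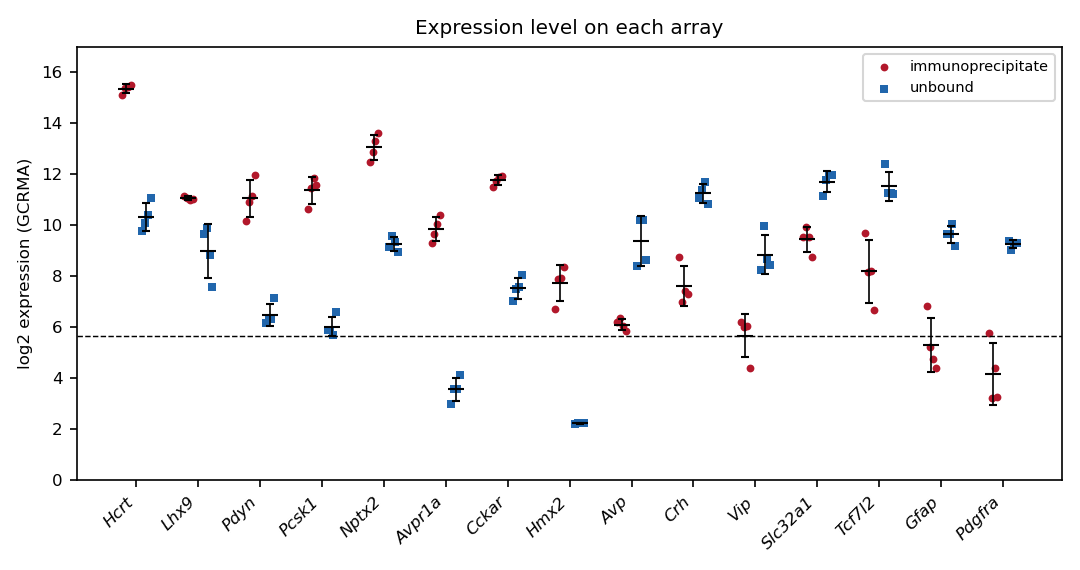
Log2 expression of 15 genes on each of the 8 arrays, with circles for the 4 immunoprecipitates, squares for the 4 unbound fractions, bars for the mean and SD, and a dashed line at the log2 of the linear value 50. Hcrt sits at 15.36 on average in the immunoprecipitate and Lhx9 varies more between unbound fractions than between immunoprecipitates.

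872 probe sets were higher and 8059 were lower in the immunoprecipitate, at a limma adjusted p below 0.05 and at least 2-fold. By gene, 493 were higher and 4598 lower. The median tested probe set changed by -0.87 on the log2 scale, so 9.76% of the calls were higher. Centred on each array's median, which moves that median by 0.92, the counts were 3666 higher and 3789 lower, with 49.2% of the calls higher. Quantile normalization, which moves it by 0.83, gave 3081 higher and 3726 lower, with 45.3% higher. On the poly-A controls, which move it by -1.97, 125 were higher and 16823 lower, with 0.74% higher. The poly-A means ran from 7.17 to 10.55 on the unbound arrays and from 10.03 to 11.22 on the immunoprecipitate arrays. The shift on that scale, used here and below, is therefore imprecise. Changes went with genomic length across genes, which are not independent replicates. The median was -0.13 in the fifth of genes with the shortest length, with 206 higher and 492 lower, and -1.54 in the fifth with the longest, with 64 and 1380. The groups did not overlap on any array for 56.9% of the tested probe sets, where chance gives 2.86% if the arrays are taken as unpaired.

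**Figure D2:**
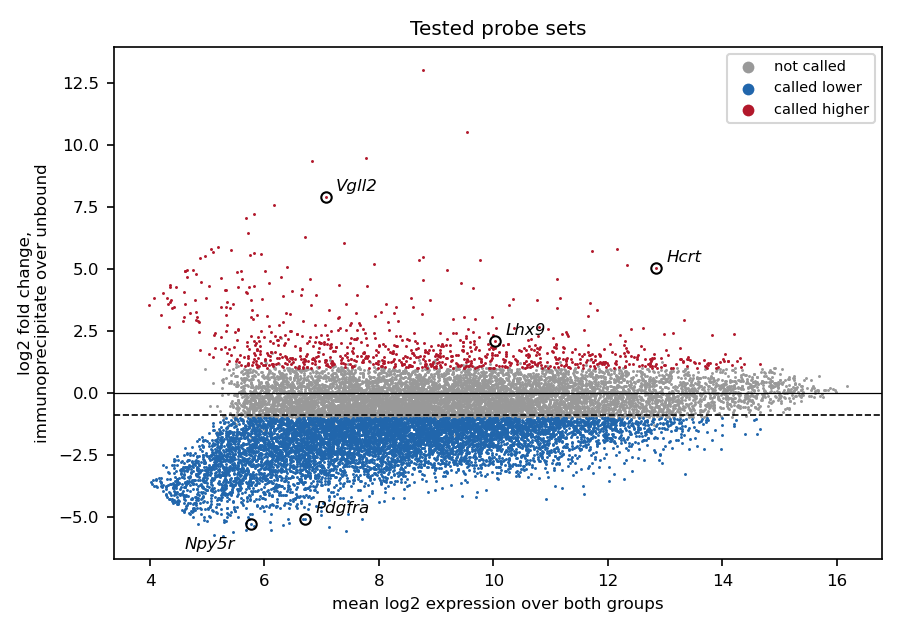
Log2 fold change of the immunoprecipitate over the unbound fraction against the mean log2 expression of both groups, 1 point per tested probe set, coloured by call, with a dashed line at the median of -0.87. Hcrt is among the most abundant of the probe sets that were higher, and lower calls outnumber higher calls, by 859 to 201 in the fifth of probe sets with the highest mean, while the counts are 3666 higher and 3789 lower after median centring.

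Among genes measured on all 8 arrays, Pcsk1, the prohormone convertase that cuts peptide precursors, rose 41.0-fold (log2 fold change 5.36 ± 0.32 SE, limma adjusted p = 1.3e-06). Most of the 15 genes taken by fitted fold were ones that the unbound fraction barely showed, so that their folds are bounds and give no order. The transcriptional cofactor Vgll2 was at least 41.0-fold higher, the membrane protein Tmem114 at least 29.0-fold, the vasopressin receptor Avpr1a at least 18.3-fold and the inflammatory protease Casp1 at least 11.7-fold. The small heat shock protein Hspb3 was at least 9.68-fold higher, the receptor Cd40 at least 7.93-fold, Pi16 at least 7.33-fold, Rnf183 at least 4.97-fold and the homeobox factor Hmx2 at least 4.19-fold. The AP-1 factor Fosl1, the hormone gene Gast, Thbs2 and Dppa2 were at least 3.84-, 2.76-, 2.69- and 2.67-fold higher. In 13 of these 15 genes, Hcrt and Pcsk1 aside, the unbound fraction was under the linear value 50 on all 4 arrays. Ighm, an immunoglobulin heavy chain gene examined after these values were seen, had 11 probe sets, of which 5 lay under 50 on all arrays, 4 had a higher and 2 a lower mean in the immunoprecipitate. 1 of the higher stood at 7.21 ± 1.17 on the log2 scale in the immunoprecipitate and at 2.27 ± 0.04 in the unbound fraction, and 1 of the lower at 4.13 ± 1.00 and 7.0 ± 1.08 (SD, n = 4 each).

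Among genes measured on all 8 arrays, Klf12 fell 18.3-fold, the calcium-binding protein Necab1 15.9-fold and the non-coding Rian 15.2-fold, the first pair named after their values were seen. Of the 10 lower genes taken by fitted fold, Pdgfra, the growth factor receptor of oligodendrocyte precursors, was at least 12.0-fold lower, with 1 of 4 immunoprecipitate arrays at or above 50. The neuropeptide Y receptor Npy5r was at least 6.89-fold lower, Tchh at least 6.35-fold, D630045J12Rik at least 6.21-fold, the cadherin Cdh19 at least 4.64-fold and the Wnt coreceptor Lrp6 at least 4.55-fold. Mpzl2, Gpr146, Dcdc2a and the glutamine transporter Slc38a3 were at least 3.65-, 2.85-, 2.77- and 2.53-fold lower. These 9 genes were under 50 on all 4 immunoprecipitate arrays, so their folds are bounds and give no order.

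The gene lists fixed before the data were examined placed hypocretin neuron genes highest. 7 of 10 tested members rose and 0 fell, while 6 rose and 3 fell on the poly-A controls, with a list median of 3.46 (camera adjusted p = 1.1e-11, and adjusted p = 0.037 with an estimated correlation). Besides Hcrt and Pcsk1, they included Pdyn, the precursor of dynorphin, at 23.7-fold and the synaptic protein Nptx2 at 14.1-fold. Rfx4, a transcription factor named here after its value was seen, rose 13.3-fold. This was the 1 list of 28 that kept its call with an estimated correlation. The vesicular glutamate transporter Slc17a6 of the same list, also named after its value was seen, gave -0.69 on the log2 scale and did not pass 2-fold. On the poly-A controls the lists of other neuropeptides, GABAergic neurons, astrocytes, oligodendrocytes, ribosomal proteins, oxidative phosphorylation and proteasome lost their calls, with adjusted p from 0.19 to 0.79. That scale shifts all genes by the same constant. Each list's median relative to all genes therefore stayed as it was, at -1.84 for other neuropeptides and 1.30 for ribosomal proteins. Camera's adjusted p on that scale, here and below, does not show a list moving against other genes.

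Other peptide systems of the hypothalamus were lower. 14 of 16 tested neuropeptide genes fell and 0 rose, with a median of -2.69 (camera adjusted p = 0.046, and adjusted p = 0.61 with an estimated correlation). Crh, the corticotropin-releasing hormone, fell 12.4-fold, the vasopressin gene Avp 9.70-fold, and Tac2 and Vip, each at or above 50 on 3 of 4 immunoprecipitate arrays, at least 10.7- and 7.30-fold. Pmch, the melanin-concentrating hormone gene of neurons that lie among the hypocretin cells, was added after its value was seen and fell 8.47-fold. Without immunoprecipitate replicate 1, unbound replicate 2 or unbound replicate 3 the list's adjusted p was 0.066, 0.051 and 0.090. In the list of dense-core vesicle and peptide processing genes 4 of 14 rose and 2 fell (camera adjusted p = 0.00017, and adjusted p = 0.26 with an estimated correlation). The amidating enzyme Pam was at least 2.99-fold higher, Scg2 rose 5.19-fold and the release factor Cadps2 fell 5.33-fold. That list had 7 higher and 1 lower after median centring, and 6 and 1 after quantile normalization. On the poly-A controls it had 2 higher and 10 lower, and Scg2 lost its call. With no filter on low values the list's camera adjusted p was 0.40.

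Markers of other neuronal classes were lower in most cases. All 6 tested markers of GABAergic neurons were lower (median -2.47, or -2.17 with genes under 50 at their bound, camera adjusted p = 0.030, and adjusted p = 0.57 with an estimated correlation). The vesicular GABA transporter Slc32a1 fell 4.84-fold, Pvalb 6.32-fold and Dlx1 at least 10.8-fold, with Dlx1 at or above 50 on 2 of 4 immunoprecipitate arrays, and Dlx2 was at least 2.64-fold lower. Without unbound replicate 3 the list's adjusted p was 0.053, and with a stricter filter 0.059. 12 of 13 thalamic markers were lower (median -2.55, camera adjusted p = 0.085, and adjusted p = 0.61 with an estimated correlation). The adjusted p was 0.0059 after median centring, 0.0074 after quantile normalization, 0.020 with the replicate block, 0.029 with no filter on low values and 0.041 without immunoprecipitate replicate 4. Tcf7l2, a factor of thalamic neurons, fell 10.2-fold, Rora 7.85-fold and Plekhg1 8.99-fold, and Lef1 was at least 8.14-fold lower. 3 of 4 habenular markers fell (median -2.47, or -1.83 with bounds, camera adjusted p = 0.23), among them Wif1 at least 1.99-fold. Of 7 monoaminergic and cholinergic markers 4 fell and 1 rose (median -1.17, or -0.82 with bounds, camera adjusted p = 0.72), and Hdc, the histamine-synthesising enzyme, fell 7.91-fold.

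Of 17 pan-neuronal genes 8 fell and 1 rose, while 5 fell and 3 rose after median centring and 16 fell and 0 rose on the poly-A controls, with a median of -0.82 and a mean of -1.13 (camera adjusted p = 0.42, and 0.036 after quantile normalization, and adjusted p = 0.62 with an estimated correlation). Relative to all genes the median was 0.03 and the mean -0.23, and camera pointed down. Map2 of dendrites fell 7.61-fold, the neurofilaments Nefm and Nefl 5.38- and 4.90-fold and the non-coding Snhg11 10.5-fold. Tubb3, a neuronal tubulin chosen after its value was seen, rose 2.23-fold, but it gave -0.81 on the log2 scale on the poly-A controls and missed 2-fold without unbound replicate 3 (0.90). Among synaptic vesicle and glutamate release genes 10 of 16 fell and 0 rose (median -1.48, or -1.41 with bounds, camera adjusted p = 0.088, 0.012 after quantile normalization and 0.029 with no filter on low values, and adjusted p = 0.57 with an estimated correlation). The synaptotagmin Syt2, at or above 50 on 3 of 4 immunoprecipitate arrays, fell at least 10.7-fold and the active zone proteins Pclo and Bsn 8.35- and 6.36-fold.

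Glial and vascular markers were mostly lower. All 16 astrocyte markers fell (median -2.34, camera adjusted p = 0.0031, and adjusted p = 0.61 with an estimated correlation), with the water channel Aqp4 down 8.21-fold and Fgfr3 7.91-fold, Sox9 at least 5.51-fold lower, and Gfap at least 13.1-fold lower with 1 of 4 immunoprecipitate arrays at or above 50. All 15 oligodendrocyte markers fell (median -2.45, camera adjusted p = 0.0032, and adjusted p = 0.61 with an estimated correlation). Ermn and Mobp, both of myelin-forming cells, fell 9.51- and 7.29-fold. 5 of 6 markers of oligodendrocyte precursors were lower (median -2.56, camera adjusted p = 0.25), with Bcas1 down 9.70-fold. All 8 markers of microglia and macrophages fell (median -2.36, or -2.04 with bounds, camera adjusted p = 0.070, and adjusted p = 0.61 with an estimated correlation). The adjusted p was 0.0062 after median centring, 0.019 after quantile normalization, 0.045 with the replicate block, 0.047 with the mean of a gene's probe sets, and 0.043, 0.041 and 0.045 without immunoprecipitate replicate 2, immunoprecipitate replicate 4 and unbound replicate 1. Laptm5 fell 7.25-fold and the complement gene C1qa was at least 5.25-fold lower. 6 of 7 endothelial and mural markers (median -1.83, or -1.36 with bounds, camera adjusted p = 0.23) and 4 of 6 ependymal and choroid plexus markers (median -1.85, camera adjusted p = 0.67) fell, with Rgs5 of pericytes down 4.48-fold and Ccdc153, on 3 of 4 immunoprecipitate arrays at or above 50, down at least 6.22-fold. Called lower after median centring were 11 astrocyte, 10 oligodendrocyte, 4 precursor, 6 microglial, 3 endothelial and mural and 2 ependymal and choroid plexus markers. After quantile normalization these counts were 12, 14, 3, 5, 3 and 2, and 1 precursor marker was higher on each of these scales. Erythrocyte genes had too few tested members.

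**Figure D3:**
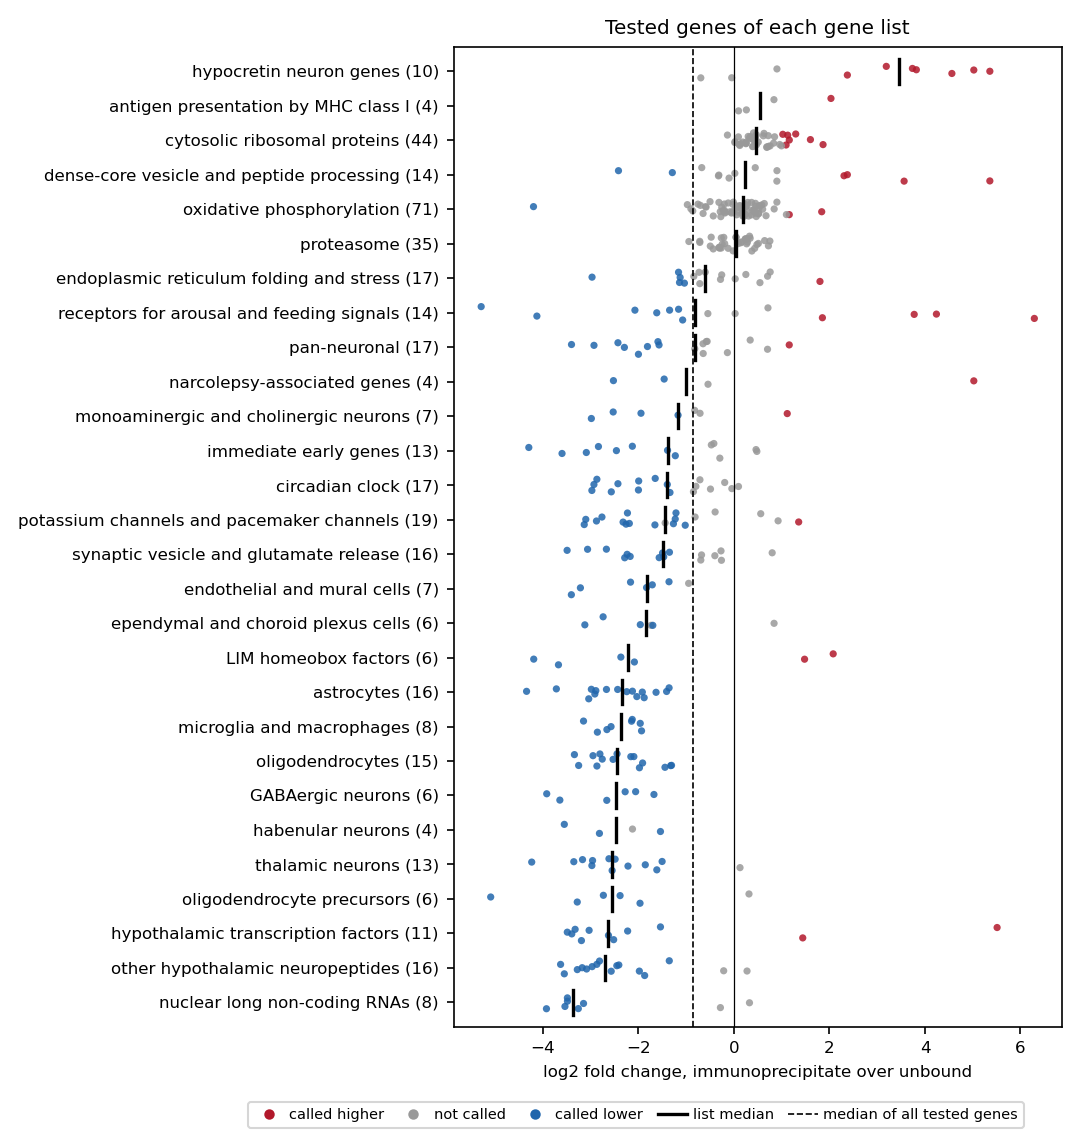
Log2 fold change of the immunoprecipitate over the unbound fraction for the tested genes of 28 lists, 1 point per gene coloured by call, with a bar at each list's median, the number of tested genes in brackets, a solid line at 0 and a dashed line at the median of all tested genes (-0.85). Hypocretin neuron genes have the highest median, 3.46, and all 39 astrocyte, oligodendrocyte and microglial genes lie below 0.

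Transcription factors of the region divided within families. Of 6 tested LIM homeobox factors 2 rose, Lhx9 and, named after its value was seen, Lhx2 at 2.79-fold, and 4 fell, while on the poly-A controls 0 rose and 4 fell. Isl1 fell 5.15-fold, Lhx8 was at least 12.1-fold lower and Lhx1 at least 1.58-fold. The list's median was -2.22 (-1.37 with bounds) and its mean -1.46, while camera pointed up relative to other genes (adjusted p = 0.97). Of 11 hypothalamic transcription factors 9 fell and 2 rose (median -2.62, or -1.54 with bounds, camera adjusted p = 0.39, and 0.041 after median centring, and adjusted p = 0.62 with an estimated correlation). Hmx2 rose, and Sim1, a factor of paraventricular neurons, and Ebf1 were at least 2.36- and 3.32-fold lower. The second that rose was Nkx2-2, 2.72-fold, named after its value was seen, and it gave -0.52 on the log2 scale on the poly-A controls.

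Receptors for arousal and feeding signals went both ways, with 4 of 14 higher and 7 lower (median -0.81, camera adjusted p = 0.085, 0.041 with the mean of a gene's probe sets and 1.1e-06 on the poly-A controls, and adjusted p = 0.57 with an estimated correlation). They were 5 higher and 3 lower after median centring, 6 and 3 after quantile normalization, and 3 and 10 on the poly-A controls. Cckar, the type A cholecystokinin receptor, rose 18.9-fold (log2 fold change 4.24 ± 0.25 SE, limma adjusted p = 1.3e-06), whereas the type B receptor Cckbr was at least 3.19-fold lower. Trhr, the receptor of thyrotropin-releasing hormone, rose 13.7-fold and was named after its value was seen. Among potassium and pacemaker channels 13 of 19 fell and 1 rose (median -1.44, camera adjusted p = 0.40, and 0.029 with no filter on low values, and adjusted p = 0.66 with an estimated correlation). The Kv1 subunits Kcna2 and Kcna1 fell 8.57- and 7.34-fold and Kcnq3 6.78-fold. 10 of 17 circadian clock genes fell and 0 rose (median -1.39, camera adjusted p = 0.14, and 0.029 with no filter, and adjusted p = 0.57 with an estimated correlation), with Bhlhe40 down 7.62-fold and Hlf 7.30-fold. Immediate early genes, induced by activity, fell in 8 of 13 cases and rose in 0 (median -1.39, camera adjusted p = 0.54), with Egr1 down 7.14-fold and Egr2 at least 4.79-fold lower.

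Genes of housekeeping complexes had medians above that of all genes (-0.85). Changes also went with genomic length, and camera compared these lists with all other tested genes, not with genes of matched length. The 2076 genes with the shortest genomic length had a median of -0.13, and the 1038 shortest had 0.03. How much of the list medians below goes with length was not tested. 7 of 44 cytosolic ribosomal protein genes rose and 0 fell (median 0.45, camera adjusted p = 4.2e-19, and adjusted p = 0.26 with an estimated correlation), while 41 rose after median centring and 36 fell on the poly-A controls. Rps27l rose 3.65-fold and Rpl37 3.04-fold. Of 71 oxidative phosphorylation genes 2 rose and 1 fell, or 1 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 1.8e-07, and adjusted p = 0.57 with an estimated correlation), while 40 rose after median centring and 66 fell on the poly-A controls. Cox7c was at least 4.48-fold lower, by a probe set at or above 50 on 0 of 4 immunoprecipitate arrays. The list averaged 13.38 to 13.61 on the log2 scale on those arrays, so that probe set may not stand for the gene's level. Ndufb1 rose at least 3.53-fold with 3 of 4 unbound arrays at or above 50. None of 35 proteasome genes passed in limma (median 0.05, camera adjusted p = 0.00063, and adjusted p = 0.26 with an estimated correlation), among them Psma3 at 0.27 and Psmb4 at 0.05 on the log2 scale, while 17 rose after median centring and 35 fell on the poly-A controls. After quantile normalization 13 ribosomal protein, 4 oxidative phosphorylation and 5 proteasome genes rose, and the oxidative phosphorylation list had a camera adjusted p of 0.14. With no filter on low values that list and the proteasome list had 0.67 and 0.88. No other list's counts changed when adjusted over the list alone.

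Genes of protein folding, immunity and narcolepsy were mixed. In the endoplasmic reticulum folding and stress list 1 of 17 rose and 5 fell (median -0.60, or -0.46 with bounds, camera adjusted p = 0.31), while 5 rose and 1 fell after median centring and 0 rose and 16 fell on the poly-A controls. Manf, a secreted stress factor, rose 3.49-fold and gave -0.16 on the log2 scale on the poly-A controls. 1 of 4 genes of antigen presentation by MHC class I rose and 0 fell (camera adjusted p = 0.0091, and adjusted p = 0.26 with an estimated correlation). After median centring and after quantile normalization 3 rose, while 3 fell on the poly-A controls. The 1 that rose on the biotinylated controls was Tapbp, which loads peptides onto class I molecules, at 4.09-fold. Its call was lost on the poly-A controls (0.07). The list's adjusted p was 0.058 after median centring and 0.11 with no filter on low values. B2m, the class I light chain, gave 0.84 and did not pass 2-fold, while it gave -1.13 on the poly-A controls. Of 4 narcolepsy-associated genes Hcrt rose and 2 fell (median -1.0, mean 0.13, with camera pointing up at an adjusted p of 0.43, and 0.0067 on the poly-A controls, and adjusted p = 0.61 with an estimated correlation). Trib2, the target of autoantibodies in some patients, fell 5.74-fold (log2 fold change -2.52 ± 0.34 SE, limma adjusted p = 0.00015).

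Nuclear long non-coding RNAs had the lowest list median. 6 of 8 fell and 0 rose (median -3.37, camera adjusted p = 0.14, and adjusted p = 0.61 with an estimated correlation). The adjusted p was 0.041 after median centring, 0.015 after quantile normalization and 0.047 without immunoprecipitate replicate 1. Rian fell 15.2-fold, Meg3 11.6-fold, Neat1 11.2-fold and Miat 11.2-fold. Malat1, named after its value was seen, fell 9.55-fold.

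RNA integrity was read from probe sets at both ends of Actb and Gapdh. The 3' minus 5' log2 signal of Actb was 3.71 ± 0.46 in the immunoprecipitate and 3.39 ± 0.33 in the unbound fraction (SD, n = 4 each), a difference of 0.32 (exact two-sided permutation p = 0.31, smallest possible 0.029). For Gapdh it was 2.80 ± 1.14 and 2.34 ± 0.68 (SD, n = 4 each), a difference of 0.46 (exact two-sided permutation p = 0.46). Paired by replicate, Gapdh was higher in the immunoprecipitate in 4 of 4 pairs (exact two-sided sign-flip p = 0.12, the smallest that 4 pairs can give) and Actb in 3 of 4 (exact p = 0.38). The 3' minus middle signal of Actb was also higher in 4 of 4 pairs (exact p = 0.12) and that of Gapdh in 2 of 4 (exact p = 0.50). Without both arrays of replicate 4 the Gapdh difference was 0.23.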

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

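The tests of the controls, of low signals, of gene length and of folds above that of Hcrt were chosen only after the result was seen. Of 235 groups of 4 values, 25 held an array far from the other 3, where chance gives 1 in 20, or 11.8. 9 of these were on immunoprecipitate replicate 4 and 5 each on immunoprecipitate replicate 1 and unbound replicate 1. Values are log2 levels, with the mean of the other 3 arrays in brackets.

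On immunoprecipitate replicate 4 Casp1 stood at 9.80 (9.0) and Nkx2-2 at 10.67 (9.48), while Vip stood at 4.40 (6.07), Nefm at 8.26 (10.04), Clic6 at 3.26 (6.33), Dynlrb2 at 5.59 (7.29), Bsn at 6.32 (6.96) and Sv2b at 5.72 (7.36). On immunoprecipitate replicate 1 Scg2 stood at 15.10 (15.49), Hdc at 7.06 (6.21), Foxa1 at 6.13 (4.49), Rian at 9.37 (7.42) and Pmch at 11.05 (9.63). On unbound replicate 1 Tcf7l2 stood at 12.39 (11.25), Dbh at 5.66 (6.29), Cckbr at 6.97 (7.42), Kcnma1 at 10.63 (8.93) and Sv2b at 10.06 (8.96). On unbound replicate 4 Vtn stood at 7.35 (8.19), Tapbp at 8.95 (8.44) and Stat5b at 9.72 (8.81). Npy5r stood at 8.55 (8.37) on unbound replicate 2 and Klf4 at 6.40 (7.59) on unbound replicate 3. The 3' minus 5' signal of Gapdh was 4.50 (2.23) on immunoprecipitate replicate 4 and 3.36 (2.00) on unbound replicate 4. The 24 poly-A controls, outside the main measurement, stood 1.97 higher in the immunoprecipitate (10.68 ± 0.60 against 8.71 ± 1.47, SD, n = 4 each, exact two-sided permutation p = 0.086).

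More probe sets were lower than higher. Of 35 splits of the arrays 1, the real one, gave as many as the 8931 called probe sets, and the highest other gave 1. Every other split mixes the fractions, which widens the spread within its groups, so low counts there follow from any large difference between fractions. The 8 splits that part all replicate pairs (highest other 0) are too few for a share under 0.05. The splits alone therefore do not exclude chance, and they do not address direction. For the 10 called lists chance cannot be excluded, since 10 of 35 splits gave as many and the highest other gave 13. An offset between the separately normalized groups is argued against by the controls, which differed by 0.0223 (SE 0.261) where the median probe set as deposited differed by -0.85. Background correction of low signals is argued against as the sole source by a ratio of lower to higher calls of 4.27 in the fifth with the highest signal (95% interval 3.71 to 5.01). A part of it stays open, since the excess was larger over all tested probe sets (8059 to 872), and median centring gave 3789 to 3666. The intervals in this paragraph resample probe sets or genes of the same arrays, so they do not measure the spread between arrays. Gene length stays open, since that ratio was 2.39 in the fifth with the shortest genes (492 to 206) but 1.91 in the tenth with the shortest (95% interval 1.54 to 2.39), where the median change was 0.03, against 1380 to 64 in the fifth with the longest genes. A biological difference, RNA of other cell types in the unbound fraction, stays open. All 16 astrocyte and all 15 oligodendrocyte markers were called lower, and 11 and 10 of them after median centring, with 0 higher. How much of the excess such RNA accounts for was not tested.

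Lhx9 stood at 9.67, 9.90, 8.81 and 7.57 on the unbound arrays. In the normalized values the proteasome genes showed no lower signal on unbound replicate 4, with a mean deviation of -0.00836 (SE 0.0508 over 35 genes). The unbound arrays were normalized together, which evens out such a difference. A lower signal of all genes before that step cannot be judged from these values. A smaller share of thalamus in the tissue of replicate 4 could lower Lhx9 and stays open, since the thalamic list deviated by -0.557 (SE 0.101 over 13 genes), under the -0.5 set beforehand by less than 2 SE. Ependymal and choroid plexus genes averaged 6.67 there, against 9.29, 10.36 and 10.30 on unbound replicates 1, 2 and 3. Habenular genes deviated by -0.894 (SE 0.525 over 4 genes) and hypothalamic transcription factors by 0.380 (SE 0.201 over 11 genes). Astrocyte genes deviated by 0.010 (SE 0.067 over 16 genes). No biological explanation was tested.

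Some folds exceeded that of Hcrt, whose upper 95% limit was 48.0-fold. RNA of hypocretin neurons alone stays open. 4 probe sets had a bound above that limit, up to at least 783-fold, and 0 of them had a gene symbol. Hcrt in the immunoprecipitate, however, lay 0.88 below the lowest maximum of the immunoprecipitate arrays on the log2 scale, so its own fold may be compressed. RNA of antibody-producing cells carried by the antibody may be a source and stays open, since 1 of 59 immunoglobulin and B-lineage probe sets was at or above 50 on all 4 immunoprecipitate arrays and no unbound array (one-sided Fisher exact p = 0.21); Ighmbp2, matched by name only, was taken off that list after its values were seen. No biological explanation was tested.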

How the results depend on the processing

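The shift on the poly-A controls and leaving out both arrays of replicate 1 or of replicate 4 were tests chosen only after the result was seen. Of 134 named genes, 114 kept their call and 133 never changed sign under those alternatives listed beforehand in which they were tested. Other fold thresholds were applied to counts of probe sets only, not to named genes. With the stricter filter on low values 117 named genes were tested, and all kept their call. Named genes that this filter removed were not counted as changed. Median centring gave 3666 probe sets higher and 3789 lower with 8 lists lower, and quantile normalization 3081 and 3726 with 9 lists lower. With no filter 1402 were higher, with 2 lists higher and 8 lower, a set that tests more probe sets. No fold threshold gave 1489 higher, and at least 4-fold 257 higher and 3714 lower. An estimated correlation left 1 list higher and 0 lower. Fry, which tests against 0 and not against other genes, called 20 lower where the median gene stood at -0.85. On the poly-A controls 125 were higher and 16823 lower, with 0 lists lower and Lhx9 at 0.11 (limma adjusted p = 0.80, range 0.0004 to 0.80 over 19 alternatives). A constant shift of this kind cannot move a list's median relative to all genes. That scale also turned Manf (-0.16), B2m (-1.13), Rps27l (-0.10), Rpl37 (-0.36), Rpl37a (-0.67), Rps10 (-0.81), Ndufb1 (-0.13), Ndufa7 (-0.81), Psma3 (-1.70), Psmb4 (-1.92), Lhx2 (-0.49), Nkx2-2 (-0.52), Tubb3 (-0.81) and Stat5b (-0.13). Psmb4, not called, gave -0.053 after quantile normalization, -0.23 to 0.32 when arrays were left out, with -0.23 without immunoprecipitate replicate 1, -0.08 and -0.10 without unbound replicates 3 and 4, and 0.32 without immunoprecipitate replicate 4. The cause was not tested.

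Leaving out each array gave 725 to 1068 higher, 6929 to 9028 lower, Hcrt at 4.90 to 5.25, Lhx9 at 1.59 to 2.49, 6 lists higher throughout, 2 (without unbound replicate 3) to 6 lower, and 3' minus 5' differences of 0.18 to 0.50 for Actb and -0.11 (without immunoprecipitate replicate 4, whose unbound partner stayed in) to 0.80 for Gapdh. Without both arrays of replicate 1 the counts were 1009 and 7641, and without those of replicate 4 they were 878 and 7282 with Lhx9 at 1.70; the 3' minus 5' differences were then 0.08 and 0.32 for Actb and 0.54 and 0.23 for Gapdh. The replicate block called 931 higher and 8192 lower, added the thalamic and microglial lists and changed no other call of named genes or lists. Signals near the background limit the folds given as bounds.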

Other observations

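The genes named in this part were chosen only after the result was seen, as were the counts of immunoglobulin genes on 3 arrays and the tests of single immunoprecipitates. Among 8417 genes at or above 50 on all 8 arrays, 353 were higher and 3151 lower. The small GTPase Rrad rose 14.2-fold and the imprinted gene Nnat 12.3-fold. The lysosomal fucosidase Fuca1 rose 10.6-fold (limma adjusted p = 2e-06). The zinc finger factor Plagl1 rose 5.38-fold but lost its call on the poly-A controls (0.46 on the log2 scale).

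Of 20 genes that neighbour Hcrt 6 were tested. Stat5b rose 3.56-fold (limma adjusted p = 0.0029) but gave -0.13 on the log2 scale on the poly-A controls, and Nkiras2 fell 2.26-fold (limma adjusted p = 0.0075) but lost its call after median centring (-0.25) and quantile normalization (-0.12). Among 1033 tested probe sets without a gene name 35 were higher and 594 lower. Among the unnamed ones that were higher, the largest bound was at least 783-fold higher and the next at least 563-fold higher.

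5 of 59 immunoglobulin and B-lineage probe sets were at or above 50 on at least 3 immunoprecipitate arrays and on no unbound array, against 202 of 34899 other named probe sets. No p is given, since this minimum of 3 arrays was set after the values were seen and 2 of the 5 probe sets belong to Ighm. 1 of 59 showed the opposite, at or above 50 on at least 3 unbound arrays and on no immunoprecipitate array, as did 1820 of the others. Of the 5 probe sets seen in the immunoprecipitate only, that of Jchain stood at 6.22 ± 0.98 in the immunoprecipitate and 2.25 ± 0.19 in the unbound fraction (SD, n = 4 each).

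Immunoprecipitate replicate 1 lay nearer the unbound fraction than the others. Probe sets called higher deviated there by a median of -0.48 and those called lower by 0.40, against 0.09, 0.20 and 0.19 and against -0.05, -0.08 and -0.22 on the other arrays.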
